A study of Homo sapiens with 39 samples.

How the data were processed

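The series measured messenger RNA in HEK293 cells, a human embryonic kidney cell line, that stably carried the delta opioid receptor. Per the labels' protocols, cells were kept in medium with 10% fetal bovine serum, RNA was column-purified and treated with DNase, and the libraries of the 1.5 h samples were made with a kit that primes at the 3' end of polyadenylated RNA. The 6 h libraries were made from total RNA with a stranded kit; these 12 libraries in 4 groups are not analysed here. Per the labels, the 27 libraries of the 1.5 h time point fall into 7 groups. Control, SNC80, DPDPE, ICI and ISO have 3 libraries each, numbered 1 to 3. A further set lettered A to F holds 6 libraries of ICI and 6 of ICI with SNC80. The series' design text speaks of triplicates, and how many libraries entered the table of ICI with SNC80 against ICI is not given in the sources used here.

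Per the submitters' processing notes, the tools were bcl2fastq 2.20.0, STAR 2.6.0c and 2.7.0f, HTSeq 0.9.1, edgeR 3.28.1 and limma 3.38.2, with the genome build hg38. The notes give no role or order for these tools, and which version served which set is not given in the sources used here. The values analysed are 5 tables of the authors' own comparisons at 1.5 h. Per the file headers, each gives for every gene a log2 fold change, a mean log2 expression, a p-value and an adjusted p-value, all computed by the authors with limma-style column names. Values of single libraries were not used here, so the depth per library is unknown and no mean, standard deviation or count of replicates could be attached to a value. The deposited adjusted p-value was checked to be the Benjamini-Hochberg adjustment of the deposited p-value, with a largest absolute difference of 6.21e-05. The authors' filter on low expression is not given in the sources used here. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

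Each of the 4 tables against control held 15946 genes after 1 repeated gene row was dropped, and the table of ICI with SNC80 against ICI held 15793. The sets share 15018 genes. In each of the SNC80 and DPDPE sets, 18 symbols had been turned into dates, so genes were joined by Ensembl identifier and symbols taken from the other tables. Gene positions, transcript lengths and GC content came from GENCODE release 29 on the same build, which held 16702 of the 16721 identifiers. The 4 control tables carry the same mean expression per gene, as a single fit of 15 libraries in 5 groups would give.

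The deposited log2 fold change was read as the first-named condition minus the second, and all values below were turned to treated minus reference. For the control tables the values favor this sign without proving it, since the floor of the libraries is unknown. With it, the lowest group level implied by the mean expression is -4.15 on the log2 scale; with the opposite sign LINC00473 would lie at -6.52 and PCK1 at -5.22 in the ISO libraries, although the lowest deposited mean is -2.84. For the table of ICI with SNC80 against ICI no such check exists, and its sign rests on the same naming order.

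A gene was called at an adjusted p-value under 0.05 in the authors' deposited table. Differences between 2 tables were tested here per gene as the difference of the log2 fold changes, with a standard error for each taken from the log2 fold change and the normal deviate of its p-value, summed as independent, and Benjamini-Hochberg adjustment. This is conservative for tables that share controls and for small p-values. An alternative chosen after seeing the data used the t distribution with 20 degrees of freedom, the value at which the 4 control tables gave each gene the most similar standard error, and treated SNC80, DPDPE and ISO as parts of 1 fit. The comparison of ISO with SNC80 was also added after the data were seen. On simulated tables of 15018 genes, the conservative test of SNC80 against DPDPE recovered 46 of 100 genes changed by 1 log2 unit and 82 of 100 changed by 2, with 0 false calls; the alternative recovered 67 and 90, with 11 false calls. For SNC80 with and without ICI the main test recovered 58 and 83 of 100, with 4 false calls, and the alternative 65 and 85, with 17 false calls. This simulation drew the 2 effects without correlation and gave the table with ICI 20 degrees of freedom, a value not known for it. In the data the 2 effects had r = -0.363 over genes above the median of mean expression, so false calls may be more frequent there.

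The design fixed before the data were examined foresaw library values; as the files hold comparisons, its provision for such tables was used. Before the data were examined, 26 gene lists were fixed. Each list with at least 5 tested members was tested with limma 3.58.1 (cameraPR, R 4.3.3) on the signed normal deviates with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. A list of 30 genes shifted by 1 standard deviation was recovered in 38 of 40 simulated draws, and 0 of 1000 unchanged lists were called. An estimated correlation needs library values and could not be used. Correlations of fold changes across genes stand beside 50 simulations of unchanged groups on shared controls. Genes were named by a rule fixed before the data were examined: in each comparison the 10 called genes with the largest rise and the 10 with the largest fall, the called members of the immediate early, ERK feedback and cAMP lists, OPRD1, the 3 members with the smallest p-values in each direction of other lists, the 10 smallest p-values per direction for differences, and 10 fixed genes where fewer than 10 were called. Results for 1 gene that this rule names are not reported here. Alternatives were other thresholds (0.01 and 0.1), a minimum absolute log2 fold change of 0.5, adjustment over the genes above the median of mean expression, centring on the median, a preset correlation of 0.05 and a rank-based list test. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.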

Results

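Gene expression was compared in HEK293 cells carrying the delta opioid receptor after 1.5 h with ligands. The design asked how opioid receptor activity at the cell surface and in the Golgi affects expression. The ligands were SNC80, a non-peptide agonist, and DPDPE, a peptide agonist, each at 100 nM, and ICI, a peptide antagonist, which was used at 100 uM and given 5 min ahead of SNC80. A further ligand is named ISO in the labels, without a dose. The labels list 3 libraries per group for each comparison with control and 6 per group for ICI with SNC80 against ICI; which libraries entered each table is not given in the sources used here, and depth is unknown. All fold changes are log2 values, treated minus reference, from the authors' deposited tables, whose sign convention is not stated and was inferred.

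SNC80 raised a compact set of early-response genes. In the authors' deposited table for SNC80, 38 of 15946 genes passed an adjusted p of 0.05, of which 36 rose and 2 fell. Among the called genes, the largest rises in the authors' deposited table were those of EGR3 (4.08), MAFF (3.16), EGR2 (2.54), NUAK2 (2.44), EGR1 (2.196) and DUSP5 (2.19). FILIP1L (2.17), IER3 (2.12), the unnamed gene ENSG00000259426 (2.09) and CTGF (1.85) completed the 10 largest called rises in the authors' deposited table. The adjusted p of these 10 ran from 4.14e-07 for DUSP5 to 0.0474 for EGR2. NR4A3 (2.44, adjusted p = 0.0785) and TNFAIP3 (2.03, adjusted p = 0.293) were above CTGF in the authors' deposited table but were not called. EGR1, EGR2 and EGR3 encode zinc finger transcription factors of the early growth response, and DUSP5 a nuclear phosphatase that acts on ERK. EGR1 (ENSG00000120738) lies on chromosome 5 at 138465490 to 138469315 of hg38 and had an adjusted p of 4.95e-05 in the authors' deposited table. DUSP5 (ENSG00000138166) lies on chromosome 10 at 110497838 to 110511544 and had the adjusted p = 4.14e-07 in the authors' deposited table. The 2 genes that fell in that authors' deposited table were ECEL1P2, a pseudogene, which fell by 0.74, and DDIT4, an inhibitor of mTORC1 signaling, which fell by 0.55. Called genes below the 10 largest included FOSL1 (1.68), HBEGF (1.47), ATF3 (1.25), DUSP6 (0.99), JUNB (0.85) and IER2 (0.44) in the authors' deposited table.

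Several gene lists fixed in advance rose with SNC80, and some share members: SRF, CTGF and ATF3 are immediate early genes that also stand in the SRF, YAP and cAMP lists. Of 41 tested immediate early genes, 13 rose with SNC80 in the authors' deposited table and 24 when adjusted over the list alone (camera adjusted p = 5.78e-41). The list of SRF and MRTF cytoskeletal genes had 4 of 20 members up, 10 when adjusted over the list alone (camera adjusted p = 5.44e-18), with SRF at 0.95 and FHL2 at 0.64 in the authors' deposited table. Of 23 YAP and TEAD target genes 3 rose, 6 when adjusted over the list alone (camera adjusted p = 1.75e-07): NUAK2, ANKRD1 (1.46) and CTGF in the authors' deposited table. Of 24 feedback genes of the ERK pathway 4 rose, 5 when adjusted over the list alone (camera adjusted p = 1.36e-07). Of 13 NF-kB target genes 1 rose, 2 when adjusted over the list alone (camera adjusted p = 0.000515, and adjusted p = 0.058 with the rank-based test). That gene was NFKBIA, which encodes the inhibitor IkB-alpha, at 1.24 in the authors' deposited table. The list of 35 cAMP-responsive genes had 1 member up, ATF3, and its camera adjusted p of 0.00605 became adjusted p = 0.0886 at a preset correlation of 0.05. Of markers of another cell type, 10 fibroblast markers had a median of 0.43 (camera adjusted p = 0.00101), with 0 called members by limma in the authors' deposited table. Their median against the same controls was 0.37 with ICI alone (camera adjusted p = 0.126) and 0.16 with ISO (camera adjusted p = 0.355). The 15 mitochondrially encoded transcripts had a median of 0.13 (camera adjusted p = 0.00256), also with 0 called members by limma in the authors' deposited table. Against the same controls their median was 0.11 with ICI alone (camera adjusted p = 0.0101), 0.07 with DPDPE (camera adjusted p = 0.714) and 0.05 with ISO (camera adjusted p = 0.376).

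DPDPE raised early-response genes as well. The authors' deposited table for DPDPE held 38 called genes, 37 up and 1 down. The 10 largest called rises in the authors' deposited table were EGR3 (3.32), MAFF (2.74), NUAK2 (2.31), DUSP5 (2.29), FILIP1L (2.19), ENSG00000259426 (2.18), CTGF (2.08), IER3 (1.97), EGR1 (1.96) and KLF7 (1.89). EGR2 (2.50, adjusted p = 0.0594) and NR4A3 (2.03, adjusted p = 0.399) were above KLF7 in the authors' deposited table but were not called. DDIT4 fell by 0.62 in the authors' deposited table. CYR61, a matricellular protein gene and YAP target, was called for DPDPE at 1.18 (adjusted p = 0.0113) and had 0.76 with SNC80 (adjusted p = 0.383) in the authors' deposited tables. JUN was at 0.71 with DPDPE (adjusted p = 0.0112) and 0.46 with SNC80 (adjusted p = 0.315) in the authors' deposited tables. Of 41 immediate early genes 14 rose with DPDPE, 23 when adjusted over the list alone (camera adjusted p = 1.07e-48). The SRF and MRTF list had 3 of 20 members up, 8 over the list alone (camera adjusted p = 2.95e-17), and the YAP and TEAD list 4 of 23, 8 over the list alone (camera adjusted p = 1.31e-12). The ERK feedback list had 4 of 24 members up (camera adjusted p = 6.21e-11) and the NF-kB list 1 of 13 (camera adjusted p = 0.000749). The cAMP list had 1 of 35 members up (camera adjusted p = 0.0252, and adjusted p = 0.18 at a preset correlation of 0.05). The 73 ribosomal protein genes had a median of -0.04 (camera adjusted p = 0.000749), which became adjusted p = 0.0657 at a preset correlation of 0.05. The fibroblast markers had a median of 0.40 (camera adjusted p = 0.00908).

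**Figure D1:**
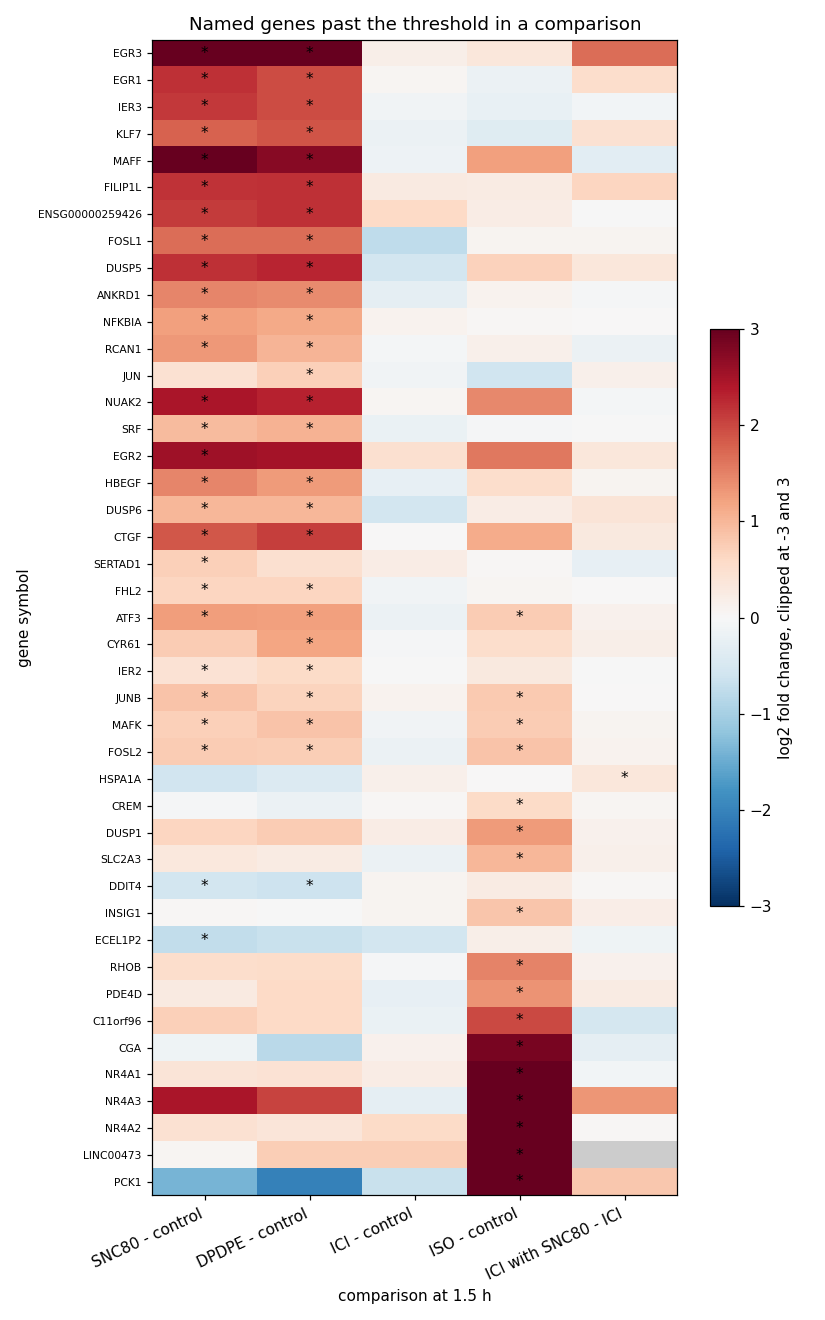
Genes named in the text and called in at least 1 comparison (rows) against the 5 comparisons at 1.5 h (columns), with color giving the log2 fold change of the authors' deposited tables, clipped at -3 and 3. Stars mark adjusted p under 0.05 and gray marks a gene without a value. SNC80 and DPDPE share most starred genes, and ISO stars another group that includes NR4A3 and PCK1. NR4A3 was also at 2.44 with SNC80 and 2.03 with DPDPE, without a star.

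The 2 agonists were compared directly at matched dose and time. No difference between SNC80 and DPDPE was detected: 0 of 15946 genes passed the test of the difference of the limma fold changes, with 54 at an unadjusted p under 0.05, and 0 passed with the standard errors of a single fit, with 377 at an unadjusted p under 0.05. Of the 44 genes called for either agonist, 32 were called for both and 44 had the same sign. Their differences, SNC80 minus DPDPE, ran from -0.42 for CYR61 to 0.76 for EGR3. The 95% interval of the EGR3 difference was -1.39 to 2.90, and that of CYR61 was -1.14 to 0.30. The median half-width of these 95% intervals was 0.58, and 31 of the 44 lay within 1 log2 unit of 0, so moderate differences in single genes were not excluded. CKM (1.40) and PTPN20 (-2.88) had the smallest p-values among the genes higher and lower with SNC80, and neither passed after adjustment.

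**Figure D2:**
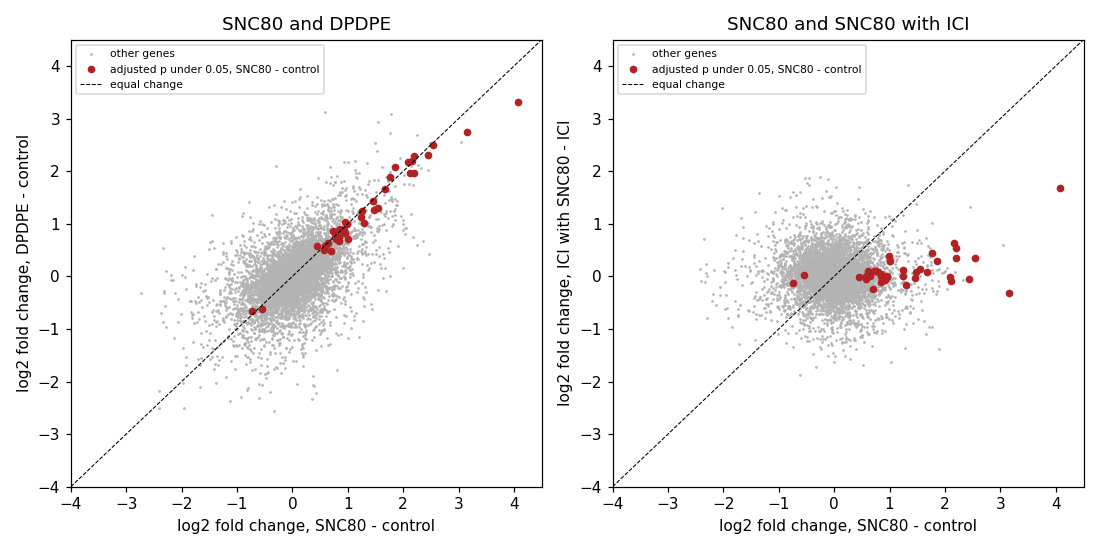
Log2 fold change of each gene with SNC80 against control (x axis) and, on the y axes, with DPDPE against control (left) or with ICI and SNC80 against ICI (right). Red points are the genes called for SNC80 and the dashed line marks equal change; EGR3 reaches 4.08 with SNC80, 3.32 with DPDPE and 1.69 with ICI present.

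ICI alone gave no called gene. In the authors' deposited table for ICI, 0 of 15946 genes passed the adjusted limma p of 0.05 and 403 had an unadjusted p under 0.05. EGR1 was at 0.05, EGR2 at 0.48, EGR3 at 0.17, JUNB at 0.11, and DUSP6 at -0.55 in the authors' deposited table. FOS was at -0.23 and NR4A1 at 0.23, with PER1 and IER2 within 0.01 of 0 in the authors' deposited table. SPRY4 had no value in the tables against control. Mitochondrially encoded transcripts formed the only called list, with 0 of 15 members called, a median of 0.11 and a camera adjusted p = 0.0101, which became adjusted p = 0.0926 at a preset correlation of 0.05. Their median was above 0 for every ligand set against these controls, so an effect of ICI cannot be told apart from a low level in the shared control libraries.

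ISO raised cAMP-responsive genes. The authors' deposited table for ISO held 27 called genes, all of which rose. The orphan nuclear receptor genes NR4A3 (5.99), NR4A2 (4.99) and NR4A1 (3.66) were among the 10 largest called rises in the authors' deposited table. So was PCK1 (5.25), the cytosolic gluconeogenic enzyme gene. LINC00473 (4.98), CGA (2.85), C11orf96 (1.98), RHOB (1.485) and PDE4D (1.35) were others of these 10 in the authors' deposited table. EGR2 was at 1.58 in the authors' deposited table without a call (adjusted p = 0.979). PCK1 (ENSG00000124253) lies on chromosome 20 at 57561080 to 57568112 and had the adjusted p = 3.36e-07 in the authors' deposited table. PDE4D encodes a phosphodiesterase that degrades cAMP. Of 35 cAMP-responsive genes 10 rose (camera adjusted p = 1.91e-35), among them CREM (0.57) and DUSP1 (1.29) in the authors' deposited table. When adjusted over the cAMP list alone, 16 rose and 1 fell. DUSP1 was also at 0.65 with SNC80 and 0.77 with DPDPE, without a call. Of 41 immediate early genes 10 rose (camera adjusted p = 1.89e-28), and 19 rose and 1 fell when adjusted over the list alone. The SRF and MRTF list had 0 of 20 members called for ISO, and the NF-kB list 0 of 13. SLC2A3, a glucose transporter gene, was called at adjusted p = 7.42e-05, and INSIG1, a sterol sensor gene, rose by 0.83 in the authors' deposited table. The list of hypoxia and glycolysis genes had 1 of 19 members up (camera adjusted p = 0.000215), which was SLC2A3. The ERK feedback list had 1 of 24 members up (camera adjusted p = 5.81e-06). At a preset correlation of 0.05 the calls of 4 further lists ended: receptors and transducers (camera adjusted p = 0.00112, then adjusted p = 0.0541), YAP and TEAD targets (0.0163, then adjusted p = 0.107), stress of the endoplasmic reticulum and Golgi (0.018, then adjusted p = 0.117) and the G2 and M phases (0.00575, then adjusted p = 0.0541).

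ISO and SNC80 were then set against each other, a comparison added after the data were seen. It called 14 genes, 6 higher and 8 lower with ISO, and 68 with the standard errors of a single fit. PCK1 (difference 6.64, standard error 1.04), NR4A2 (4.54, standard error 0.73) and NR4A1 (3.27, standard error 0.78) were higher with ISO. IER3 (-2.34, standard error 0.37), EGR1 (-2.37, standard error 0.48), NFKBIA (-1.20, standard error 0.23) and JUN (-1.07, standard error 0.22) were lower. JUN was not called with SNC80 or ISO. Its difference was larger than its rise with SNC80, so its value with ISO lay under that of control. ATF3, FOSL2, JUNB and MAFK were the 4 genes that rose in the authors' deposited tables of SNC80, DPDPE and ISO alike.

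With ICI present, HSPA1A was the gene called for SNC80. The authors' deposited table of ICI with SNC80 against ICI held 1 called gene of 15793, HSPA1A, at 0.34 (adjusted p = 0.000259), with 1440 genes at an unadjusted p under 0.05. HSPA1A (ENSG00000204389) encodes an inducible chaperone, lies on chromosome 6 at 31815464 to 31817946, and has a near-identical copy, HSPA1B, so counting could split its reads and its value is uncertain. HSPA1B stood at 0.25 (adjusted p = 0.248) in the authors' deposited table. The fixed genes not called in the authors' deposited table were EGR1 (0.53, adjusted p = 0.207), DUSP6 (0.39, adjusted p = 0.214), EGR3 (1.69, adjusted p = 0.316), EGR2 (0.34), SPRY4 (0.43), JUNB (0.01), IER2 (-0.02), NR4A1 (-0.08) and PER1 (-0.03); FOS had no value there. Of 39 immediate early genes 0 were called and 2 rose when adjusted over the list alone, with a median of 0.09 and a camera adjusted p = 0.00452 that became adjusted p = 0.106 at a preset correlation of 0.05. Histone genes had a median of -0.19 with 0 of 15 called (camera adjusted p = 0.00764, and adjusted p = 0.106 at a preset correlation of 0.05). The cAMP (camera adjusted p = 0.0119), ERK feedback (0.0461) and ribosomal protein (0.0163) lists were also called, and at a preset correlation of 0.05 had adjusted p = 0.138, 0.251 and 0.278. The sign of this table follows the order of its name and could not be settled from the values.

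The effect of SNC80 was compared with and without ICI, the ligand combination with which the design addresses receptor activity at the plasma membrane and in the Golgi. The difference of the 2 effects passed the test for 16 of 15018 genes, 15 lower and 1 higher with ICI, and 1274 had an unadjusted p under 0.05. The lower genes of smallest p were IER3 (-2.21, standard error 0.34), RCAN1 (-1.47, standard error 0.25), NFKBIA (-1.23, standard error 0.21), MAFF (-3.48, standard error 0.67) and DUSP5 (-1.84, standard error 0.36). ATF3 (-1.13), HBEGF (-1.40), ANKRD1 (-1.49), SERTAD1 (-0.94) and SRF (-0.95) followed. The 36 genes that rose with SNC80 had a median of 0.02 with ICI, and 21 of the 36 were above 0; their median of 1.12 without ICI is raised by their selection in that table. The difference for EGR1 was -1.66 (standard error 0.43, adjusted p = 0.0787). The effects come from separate library sets, so set and antagonist cannot be told apart, and under the opposite sign 22 genes passed, all lower with ICI, with 12 of the 16 among them and SERTAD1 and HSPA1B not.

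**Figure D3:**
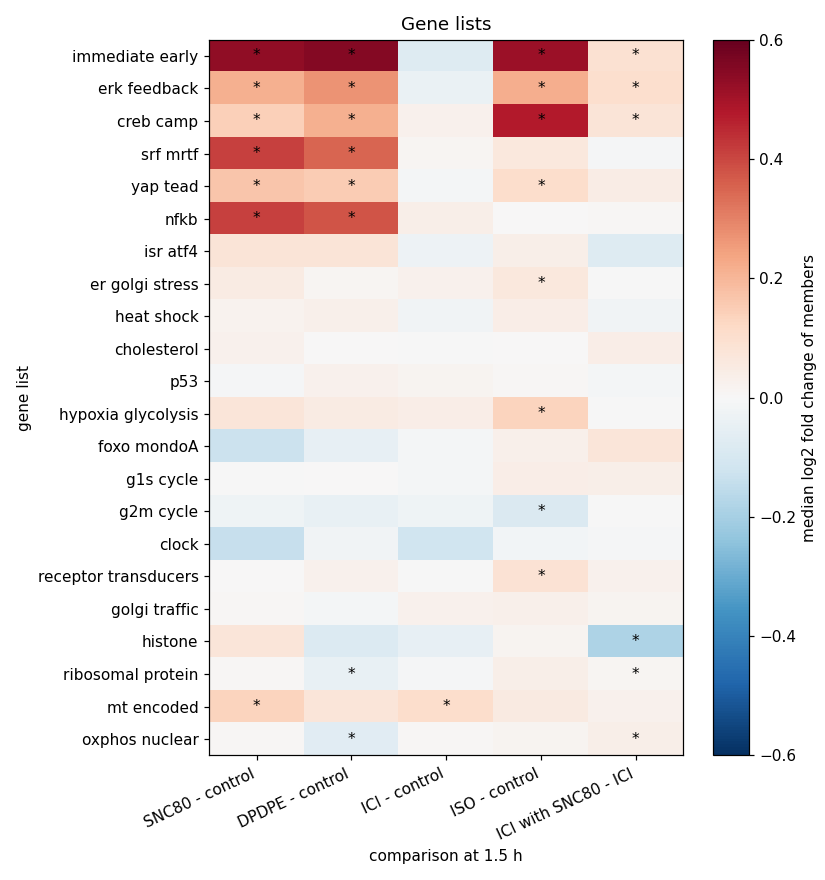
Median log2 fold change of the members (color) of each gene list tested in all comparisons (rows) in the 5 comparisons at 1.5 h (columns). Stars mark a camera adjusted p under 0.05; immediate early genes have medians of 0.53, 0.55 and 0.51 with SNC80, DPDPE and ISO.

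The responses to both agonists overlapped in 31 genes that rose and 1 that fell, where independent lists of 36 and 37 rising genes share 0.0835 genes. SNC80 and ISO shared 4 rising genes, against 0.061 for independent lists, a reference that leaves out the shared controls. At an unadjusted p under 0.05, SNC80 and DPDPE shared 164 rising and 74 falling genes, and SNC80 and ISO 65 rising genes. Unchanged groups simulated on shared controls shared 82.8 rising and 84.5 falling genes on average over 50 draws. ICI, with no called gene, shared 41 rising and 29 falling genes with SNC80. It shared 35 and 20 with DPDPE, and 42 and 24 with ISO. The simulation assumes p-values of true size, whereas ICI had 2.53% of genes under 0.05, so the simulated counts may be too high. Across genes, which are not independent replicates, the fold changes of SNC80 and DPDPE correlated at r = 0.556 beside a simulated 0.4985, with a covariance of 0.0837 beside a simulated 0.0674. Over the genes above the median of mean expression it was r = 0.764 beside a simulated 0.498, with a covariance of 0.0201 beside a simulated 0.0110. For SNC80 and ISO the correlation was 0.375 over all genes and 0.0933 above that median, both below the simulated values, with covariances of 0.0567 and 0.0023. Above that median, the other pairs on the same controls had covariances from -0.0011 (SNC80 and ICI) to 0.0089 (ICI and ISO). These lower covariances argue against shared control libraries as the source of the excess of SNC80 and DPDPE over those genes. They do not separate a shared response to the agonists from a difference in handling between libraries, which was not tested. Over all genes the controls could not be split, so part of the excess may come from shared control libraries. OPRD1, the receptor gene itself, was at 0.06 with SNC80, -0.07 with DPDPE, -0.33 with ICI and 0.45 with ISO in the authors' deposited tables. It was at -0.64 with ICI and SNC80, with no call in any comparison. Its mean log2 expression was low, at 1.91 in the comparisons with control and 0.63 in that of ICI with SNC80. Whether reads of the introduced receptor were counted under this gene is not given in the sources used here. The list of 33 Golgi traffic genes was not called in any comparison, with the smallest camera adjusted p = 0.355 for ISO.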

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

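The tests of the explanations in this part that were chosen only after their results were seen are those of the table's sign, of a chaperone response and of the spread behind the small p-values for ICI; the tests of length, GC content and transcript classes were written down first. The effect of SNC80 differed with and without ICI in 16 genes, by a test of the difference itself. The differences, with minus without ICI, were -2.21 for IER3, -1.47 for RCAN1, -1.23 for NFKBIA, -3.48 for MAFF, -1.84 for DUSP5, -1.13 for ATF3, -1.40 for HBEGF, -1.49 for ANKRD1, -0.94 for SERTAD1 and -0.95 for SRF; SERTAD1 did not pass under the opposite sign of the table of ICI with SNC80. HSPA1B was the gene whose SNC80 effect was higher with ICI than without, by 0.77, which rests on the sign taken for the table. This difference was larger than its rise with ICI present, so its value with SNC80 alone lay under that of control. That fall was not a call, as 0 of 18 heat shock list members were called for SNC80 against control. Library set and antagonist changed together, which leaves a difference between the sets open. Mean log2 expression in the comparisons with control and in that of ICI with SNC80 lay far apart for some genes. It was 3.51 and 7.18 for RPS10 and 11.39 and 8.79 for COX7A2, while others such as AURKA (8.02 and 8.16) were close.

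Abundant genes leaned in opposite directions in SNC80 against control and in ICI with SNC80 against ICI, with r = -0.363 across 7248 genes; the table of ICI with SNC80 had r = -0.227 with DPDPE, 0.249 with ICI and 0.246 with ISO, so DPDPE leaned as SNC80 did and ICI and ISO the other way. Trends on transcript length and GC content do not account for it, since the correlation was -0.325 after removing them. Ribosomal protein and respiratory chain transcripts do not either, since it was -0.357 without them. A reversed sign of the second table may be the source and cannot be told apart. The genes that rose with SNC80 had a median of 0.0241 there with a bootstrap standard error of 0.0356, but a median cannot fix a sign. As read here, 21 of these 36 genes were above 0, as were 7 of the 8 with an unadjusted p under 0.05. Of 39 immediate early genes, 26 were above 0 (camera adjusted p = 0.00452, and adjusted p = 0.106 at a preset correlation of 0.05). These values lean toward the sign used here but do not settle it. A difference between library sets also stays open, and an effect of SNC80 at receptors that ICI does not reach was not tested.

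HSPA1A was the gene called with ICI and SNC80. A response shared by all chaperones is argued against by the other 17 heat shock list members, whose median was -0.0294 with a standard deviation of 0.116, against 0.34 for HSPA1A. Adjusted over the list alone, 3 members rose, HSPA1A and HSPA1B (0.25) among them, and 4 fell, so a response of some members stays open. A trend on length or GC content is argued against by the value of 0.316 left after removing it. Reads shared with HSPA1B and the sign of the table also remain open.

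ICI against control gave fewer small p-values than chance would, 2.53% of genes under 0.05, and the other control tables were also under 5%, at 4.70% for SNC80, 3.68% for DPDPE and 3.73% for ISO. The standard deviation of the signed t over the genes above the median of mean expression was 0.832 there and 0.785 for SNC80 against DPDPE, where 1 is the value of a spread that holds for these libraries. A wider spread among the SNC80 and DPDPE libraries is argued against by the 0.785. Variation between replicate numbers shared by all groups and left in the residual spread may be a source, since both values lie below 1. That hypothesis needs library values to be tested directly, and no biological explanation was tested.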

How the results depend on the processing

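No paired analysis was possible because the values used are fold changes and p-values of whole comparisons, with no column per library. For the same reason other normalizations, filters, pseudocounts, count tests, a joint fit, leaving out each replicate, an estimated correlation and other splits of the samples were not run, and depth is unknown. The alternatives of standard errors, of expression limits and of the table's sign were chosen after seeing the data. Gene counts for ICI and for SNC80 against DPDPE were 0 under each alternative run. At an adjusted p under 0.01, SNC80 and DPDPE had 25 genes each, and ISO against SNC80 had 9. ICI with SNC80 had 3 genes at an adjusted p under 0.1 (HSPA1A, HERPUD1 and CLU, the last named after its value was seen), 3 with adjustment over the genes above the median of mean expression, and 0 with a minimum absolute log2 fold change of 0.5. The difference of SNC80 effects with and without ICI had 38 genes with t for the SNC80 table. That all 16 genes were among them is fixed by construction, because t makes every standard error smaller. On simulated tables this alternative gave 17 false calls. Adjusted over the 39 genes called in either table, 39 of 39 passed, which says nothing about stability because no gene was called in both. ISO against SNC80 had 9 genes with adjustment over the genes above that median and 68 with the standard error of a single fit. With a preset correlation of 0.05, called lists numbered 0 for ICI, 4 for ISO and 0 for ICI with SNC80, and the rank-based test called 2 for the last. The rank-based test ended 8 list calls in all; that of NF-kB targets for SNC80 was the only one of them that held at a preset correlation of 0.05. At an unadjusted p under 0.05 the shared genes were 164 up and 74 down for SNC80 and DPDPE. They were 65 up for SNC80 and ISO, and 58 up for DPDPE and ISO. Simulated unchanged groups shared 82.8 up and 84.5 down on average, which may be too high. ICI shared 41 up and 29 down with SNC80, 35 and 20 with DPDPE, and 42 and 24 with ISO. The cause was not tested where it does not follow from the threshold or the number of genes. Of the called values for single named genes, 15 lost the call at 0.01, 2 at the minimum fold change and 1 with centring. Of these settings only the centring could change a sign. It changed 0 signs, but its largest shift was only 0.00668, for ISO. The adjustment over genes above the median of mean expression left 11 of 38 calls untested for SNC80, 10 of 38 for DPDPE and 10 of 27 for ISO. The opposite sign of the table of ICI with SNC80 turns HSPA1A by construction.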

Other observations

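In the table of ICI with SNC80 against ICI, small p-values gathered among abundant genes: 13.0% of genes above the median of mean expression had an unadjusted p under 0.05, against 5.21% of those below it. For SNC80 against control these shares were 4.001% and 5.39%. In the authors' deposited table the nuclear respiratory chain gene COX6C was at 0.19 and the ribosomal protein gene RPS7 at 0.15, with adjusted p = 0.170 and adjusted p = 0.172. The respiratory chain list had 0 of 30 members called, 4 up when adjusted over the list alone, and a camera adjusted p = 0.00764, which became adjusted p = 0.106 at a preset correlation of 0.05; with DPDPE its median was -0.07 and its camera adjusted p = 0.00256.

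Of the 36 genes that rose with SNC80, 8 had an unadjusted p under 0.05 with ICI and SNC80 against ICI in the authors' deposited table, 7 of them above 0. These were EGR1, EGR3, DUSP5, DUSP6, CTGF, FILIP1L and KLF7, and SERTAD1 was the one below 0. None of the 8 passed the adjusted p of 0.05. Of all genes in that comparison, 9.12% had an unadjusted p under 0.05, and 13.0% of those above the median of mean expression. Genes that rose at an unadjusted p under 0.05 both with SNC80 and with ICI and SNC80 numbered 18, against 21.5 for independent lists, so no excess was seen at that threshold.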
